A study of Mus musculus with 8 samples.

How the data were processed

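RNA from 8 whole mouse embryos at embryonic day 6.5, 4 labelled WT and 4 labelled as mutant for Axin1 and Axin2, was extracted with a column kit, amplified to cDNA with the SMART-Seq v4 kit over 12 cycles and made into libraries with KAPA Hyper Prep, per the labels' protocols. The cDNA kit copies full-length polyadenylated RNA and does not keep strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes the tools were cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3 and DESeq (no version given) with the mm10 build; their settings and the annotation release are not given in the sources used here. Whether reads mapping to several places were counted is not given there either, so the values of genes with near-identical copies are uncertain.

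The deposited table holds 1 value per gene and library for 19950 genes, with gene IDs and symbols, and the file's own name calls the values counts scaled by DESeq. The authors' values are a non-negative signal: gene counts divided by 1 size factor per library. Every column held whole multiples of 1 step, with 100% of values whole within 0.01 of a read, so the reads were recovered by dividing by the step; the steps ranged from 0.866 to 1.18 scaled counts per read. Size factors recomputed from those reads by the median-of-ratios method matched the deposited scaling. Reads assigned to genes summed to 26615732 to 36778164 per library. No gene in the table had fewer than 15 reads over all libraries. These are reads amplified by PCR without molecular identifiers, so counting intervals cover counting error only and not the spread between embryos. Replicates of a genotype were compared in pairs on recovered reads, and chi-square per degree of freedom was 18.8 to 82.6, so no pair agreed within sampling noise and each library was counted once.

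The genotypes were compared on log2(scaled count + 1) with limma 3.58.1 in R 4.3.3, with a trended variance prior, two-sided, and Benjamini-Hochberg adjustment at 0.05. Genes needed a scaled count of at least 10 in at least 4 libraries, which left 15600. Fold changes are on the log2(value + 1) scale, which understates the change of low genes; folds quoted are 2 to the power of that log2 fold change. For genes with 3 or fewer reads in a genotype, the ratio of recovered reads is given with its exact 95% counting interval. For 29 gene lists camera was run with a preset correlation of 0.01 between genes and again with an estimated correlation, beside fry, and adjusted over the lists. Camera compares the genes of a list with all others. The lists covered WNT targets, ligands and antagonists, the destruction complex, primitive streak and mesoderm types, blood, anterior streak, pluripotency, anterior neural and visceral endoderm genes, the extraembryonic lineages, germ cells, BMP, NODAL and FGF responses, mesenchymal genes, stress and proliferation, and maternal decidua and blood. No list passed with an estimated correlation, the smallest adjusted p being 0.0502 for blood and endothelium, whereas 14 passed with the preset one and 13 with fry.

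The grouping, tests, gene lists and most alternatives were fixed before the data were examined, as was the rule for named genes. It takes Axin1 and Axin2, the 12 largest increases and 12 largest decreases among genes past the threshold without overlap between genotypes and with a mean of at least 50 in the higher genotype (predicted genes, pseudogenes, Xist and Y-linked genes left out), a set of key gastrulation genes whatever their result, and from each list up to 4 members past the threshold with the smallest p, or 2 where none passes. Other list members are named to make up small counts and were chosen after their values were seen. Coordinates come from GENCODE M21 on GRCm38, the assembly of mm10, by gene ID without its version; 19878 of the 19950 IDs matched. That release is not known to be the one used for counting.

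The script was tested on simulated data for the mutant against WT comparison: negative binomial counts for the 19950 genes at the real means and library sizes. Among 15678 genes tested, limma called 46.8% of 94 genes changed 2-fold and 77.8% of 99 changed 4-fold. Of its calls, 4.72% were unchanged genes. Far fewer genes were changed there than the 2431 that passed in the real comparison, so these shares need not carry over. Camera found the 1 changed list and none of 28 unchanged lists, in data without correlated genes. Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, median centring, quantile normalization, array weights, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, each library left out, and the other list tests. On the recovered reads edgeR called 2430 genes and DESeq2 3438, against 2431 with limma. Added after seeing the data were a fit on the 6 libraries with Y-linked transcripts, a fit without mutant replicates 4 and 5, and the mean of the maternal decidua list as a covariate.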

Results

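Whole mouse embryos at embryonic day 6.5, when gastrulation begins, were profiled by bulk RNA sequencing to compare gene expression between WT embryos and embryos mutant for both Axin1 and Axin2. The Axin proteins are scaffolds of the complex that marks β-catenin for destruction and so restrain canonical WNT signalling, and the series asks how their loss affects WNT signalling and mesoderm. The table held 4 WT and 4 mutant libraries, each titled as an embryo. The replicate numbers used here, 1, 2, 4 and 5 within each genotype, are those of the column names. The titles number the same embryos 1 to 4 in that order. Reads assigned to genes ranged from 26615732 in WT replicate 5 to 36778164 in WT replicate 4, so counting error was small for all but the lowest genes. Values are gene counts scaled by 1 size factor per library and are given as mean ± SD over the 4 libraries of a genotype. The litter of each embryo is not given in the sources used here, so p-values measure the spread between these embryos only. All 4 mutant libraries and WT replicates 1 and 4 carried Y-linked transcripts (summed Ddx3y, Eif2s3y, Kdm5d and Uty of at least 5244), whereas WT replicates 2 and 5 had at most 14.2.

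Axin1 transcripts fell in the mutants to less than the lowest WT library. The gene (ENSMUSG00000024182.16, chromosome 17, 26138688 to 26195811 on the plus strand of GRCm38) had a scaled count of 4565 ± 1081 in WT and 1996 ± 204 in the mutants (log2 fold change -1.16, SE 0.18, limma adjusted p = 0.00269), a 2.24-fold decrease. Transcripts were still counted in each mutant library, from 1721 to 2203, and WT replicate 4 was the lowest WT library at 2963 against 4884 to 5274 in the others. Axin2 (ENSMUSG00000000142.15, chromosome 11, 108920349 to 108950783, plus strand), which is itself a transcriptional target of canonical WNT signalling, had 266 ± 32.6 in WT and 370.5 ± 113 in the mutants and did not pass the test (log2 fold change 0.44, SE 0.20, limma adjusted p = 0.19). Its highest value was 539 in mutant replicate 1. Exons of Axin2 overlap those of Gm11670, and the library kit does not mark strand, so reads in the overlap cannot be told apart. The labels do not give the allele structures, and counts per whole gene cannot show which exons the remaining transcripts held, so the Axin2 value does not check its genotype.

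**Figure D1:**
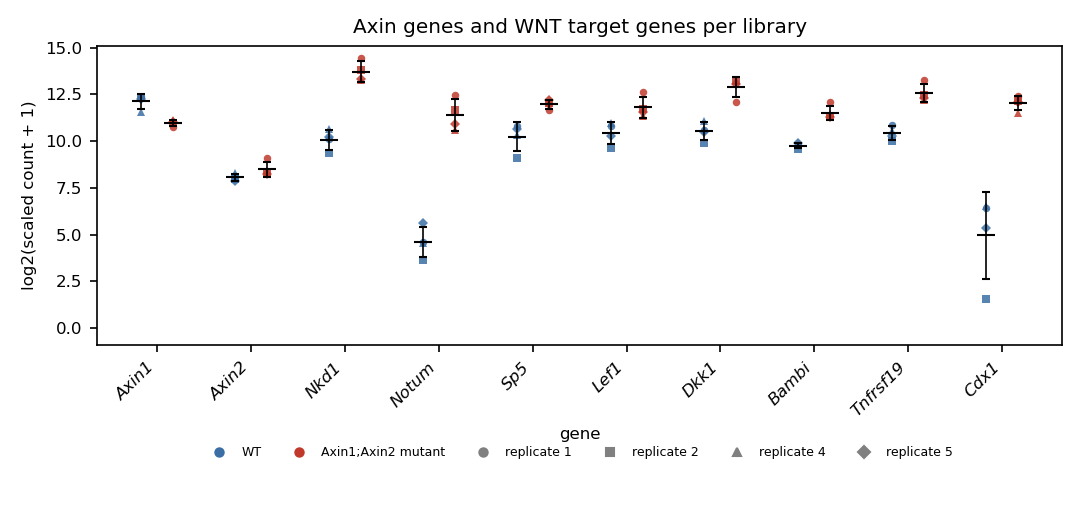
Scaled counts on the log2(value + 1) axis for Axin1, Axin2 and 8 WNT target genes in each library, WT in blue and mutant in red, with the symbol giving the replicate and black bars the mean ± SD of 4 libraries. Axin1 lay lower in the mutants (log2 fold change -1.16), Axin2 overlapped between genotypes, and Nkd1 and Notum were higher in each mutant library than in any WT library.

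The comparison of mutant with WT embryos asks how gene expression depends on the Axin genes, and expression differed widely. Of 15600 genes tested, 1253 were higher and 1178 lower in the mutants, and 763 and 538 of these by at least 2-fold. Homeobox and caudal genes led the increases: Cdx4, Cdx1, Hoxb6, Hoxd9, Hoxb1 and Hoxb2 were among the 12 largest, with Hapln1, Fendrr, Bmp5, Notum, Notumos and Bgn. Cdx4, a caudal-type homeobox gene of posterior tissues (chromosome X, 103321398 to 103330592), had 3 reads in all WT libraries together and 10262 in the mutants, a ratio of 3578 with a counting interval of 1224 to 17351. Hoxb6 had 1 read in WT and 2215 in the mutants (ratio 2317, counting interval 415 to 91542). Hoxd9 rose from 3.1 ± 3.1 to 883 ± 84.4 (log2 fold change 8.02, SE 0.45, limma adjusted p = 2.79e-05) and Bmp5, a BMP ligand, from 1.54 ± 2.48 to 217 ± 45.1. The largest decreases were in Foxd3, an epiblast transcription factor (811 ± 253 in WT, 8.13 ± 14.4 in the mutants, log2 fold change -7.88, SE 0.99, limma adjusted p = 0.000982), Slc35d3, Lefty1, Rgs8, Slc7a3, Platr10, Sez6, Foxr2, Ptk6, Otx2, Miat and Klhl14, from 24.3-fold for Klhl14 to 235-fold for Foxd3 on the log2(value + 1) scale. For Foxd3 the log2 fold change was -8.95 without mutant replicate 5, -9.60 without mutant replicates 4 and 5, -6.90 with array weights, -6.71 with edgeR, -6.65 with DESeq2 and -11.09 with the decidua covariate, the mean log2 value of the maternal decidua list. For Klhl14 it was -4.60 in all 8 libraries, -3.61 without mutant replicate 1, -5.79 without mutant replicates 4 and 5, -3.96 with array weights and -6.07 with the decidua covariate. With a pseudocount of 5 the log2 fold change was -6.42 for Foxd3, -3.80 for Klhl14, -4.92 for Lefty1, 6.84 for Hoxd9, 5.13 for Bmp5, 4.20 for Msgn1, 3.97 for Hsd3b6, 4.72 for Acta2, 2.38 for Gfi1b and 1.89 for Prdm14. No overlap between the 4 WT and 4 mutant values was seen for 2320 of the 2431 genes past the threshold, and for 22.4% of the tested genes against 2.86% by chance. Centring each library on its median gave 1029 higher and 1590 lower genes, 39.3% higher against 51.5% with the deposited scaling. Leaving out WT replicate 1 or WT replicate 4 gave 734 or 743 lower genes. The 6 libraries with Y-linked transcripts gave 528 higher and 493 lower, and the fit without mutant replicates 4 and 5, which had the most maternal decidua transcripts, gave 707 and 723. With the decidua covariate 148 were higher and 143 lower. Of the 2431 genes past the threshold 970 also passed in the 6 libraries with Y-linked transcripts. Of the named genes that the rule gave, 24 lost their call in those 6 (adjusted p 0.0516 to 0.232): Lefty1, Foxr2, Otx2, Klhl14, Nodal, Lef1, Cer1, Sox2, Fgf5, Wnt3a, Fgf4, Lhx1, Tet2, Prdm14, Gata3, Gjb2, Prdm1, Cfc1, Aen, Ccnb2, Plk1, Egln3, Phgdh and Hoxa10. Without mutant replicates 4 and 5, 19 did (adjusted p 0.0505 to 0.26): Tbx6, Sp5, Sox2, Wnt3a, Fgf4, Tet2, Prdm14, Lama1, Gata3, Gata2, Hsd3b6, Prdm1, Dnd1, Gdf3, Etv4, Aen, Ccnb2, Plk1 and Ldha.

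Most WNT target genes were higher in the mutants. Of 18 tested members of the list, 13 rose and none fell with limma, edgeR or DESeq2 (camera adjusted p = 8.84e-11, and adjusted p = 0.174 with an estimated correlation). 14 higher and 0 lower passed when adjusted over the list alone. Nkd1, a feedback inhibitor of the pathway (chromosome 8, 88521354 to 88594884), rose 12.4-fold, from 1135 ± 381 to 14287 ± 5913 (log2 fold change 3.64, SE 0.31, limma adjusted p = 0.000171). Notum, a secreted enzyme that inactivates WNT ligands, rose from 26.1 ± 15.2 to 3105 ± 1897 (log2 fold change 6.82, SE 0.48, limma adjusted p = 7.65e-05). Its exons overlap those of the antisense gene Notumos, and the library kit does not mark strand, so their reads cannot be told apart. Without mutant replicates 4 and 5 its log2 fold change was 7.48. Cdx1 rose 135-fold, but 61.4-fold without WT replicate 2, which held 1.89 against 40.2 to 90.1 in the other WT libraries. Its log2 fold change was 5.94 without WT replicate 2, 5.57 in the 6 libraries with Y-linked transcripts, 6.29 with edgeR, 6.32 with DESeq2 and 8.30 with the decidua covariate, against 7.08 in all 8. Dkk1 rose 5.19-fold, Tnfrsf19 4.45-fold, Sp5 3.38-fold, Bambi 3.37-fold and the transcriptional effector Lef1 2.6-fold (adjusted p = 0.0239), a call lost without WT replicate 5 (adjusted p 0.0651; 0.0063 to 0.157 over all settings). Apcdd1, Lgr5, Rnf43, Nkd2 and Tcf7 also rose. The Rnf43 call was lost without WT replicate 1 or 5 or mutant replicate 1, 2 or 5, with quantile normalization, in the 6 libraries with Y-linked transcripts and without mutant replicates 4 and 5 (adjusted p 0.0552 to 0.149), that of Nkd2 without mutant replicates 4 and 5 (adjusted p 0.0822) and that of Tcf7 in the 6 libraries with Y-linked transcripts (adjusted p 0.0931). WT replicate 2 also held the lowest WT value of Lgr5 (18 against at least 101), whose log2 fold change of 3.43 was 2.73 without WT replicate 2, 2.55 in the 6 libraries with Y-linked transcripts and 4.82 with the decidua covariate. T, Znrf3, Sp8, Myc and Ccnd1 did not pass the threshold. In the 6 libraries with Y-linked transcripts 11 of the 18 were higher (list median 1.23 against 1.76), and without mutant replicates 4 and 5, 10 were (median 1.89). With the decidua covariate 5 of 18 were (median 2.15).

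The genes that carry and modulate the WNT signal moved in both directions. Among 27 ligands and receptors 9 rose and 4 fell (10 higher and 4 lower adjusted over the list alone, and over all genes 8 and 4 with edgeR and 10 and 4 with DESeq2), and the list as a whole did not pass camera (adjusted p = 0.23). It passed, higher, on the DESeq2 values (adjusted p = 0.0258) and with fry (adjusted p = 0.027; 0.0258 to 0.644 over all settings). Wnt4 rose from 18.1 ± 11.2 to 628 ± 223, Wnt5a 7.52-fold, Wnt5b 5.37-fold, and the receptor gene Fzd10 14.7-fold (log2 fold change 3.87, SE 0.35, limma adjusted p = 0.000217). Fzd2, Fzd7, Fzd8 and Rspo1 fell, and the Fzd8 call was lost in the 6 libraries with Y-linked transcripts (adjusted p 0.0675). Of 10 secreted antagonists, Notum, Dkk1 and Dkk3 (13.1-fold) rose, and Sfrp2 (3.17-fold), Cer1, Sfrp1 and Shisa2 fell (camera adjusted p = 0.544, and 0.0451 with fry). 3 higher and 4 lower passed when adjusted over the list alone. The Sfrp1 call was lost without WT replicate 1, 2, 4 or 5 or mutant replicate 4 and in the 6 libraries with Y-linked transcripts (adjusted p 0.0606 to 0.171) and the Shisa2 call without WT replicate 1, 2 or 5 or mutant replicate 1, 2 or 4, with array weights and in the 6 libraries with Y-linked transcripts (adjusted p 0.0642 to 0.236). None of 15 genes of the destruction complex and β-catenin passed the threshold with limma (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.544), among them Ctnnb1, Apc and Gsk3a. At an unadjusted p under 0.05 limma gave 1, edgeR called 0 and DESeq2 1. Gsk3b was 1459.9 ± 160.1 in WT and 1767 ± 88.1 in the mutants (limma adjusted p = 0.0739), and passed with DESeq2 (adjusted p = 0.0336; 0.0336 to 0.709 over all settings).

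**Figure D2:**
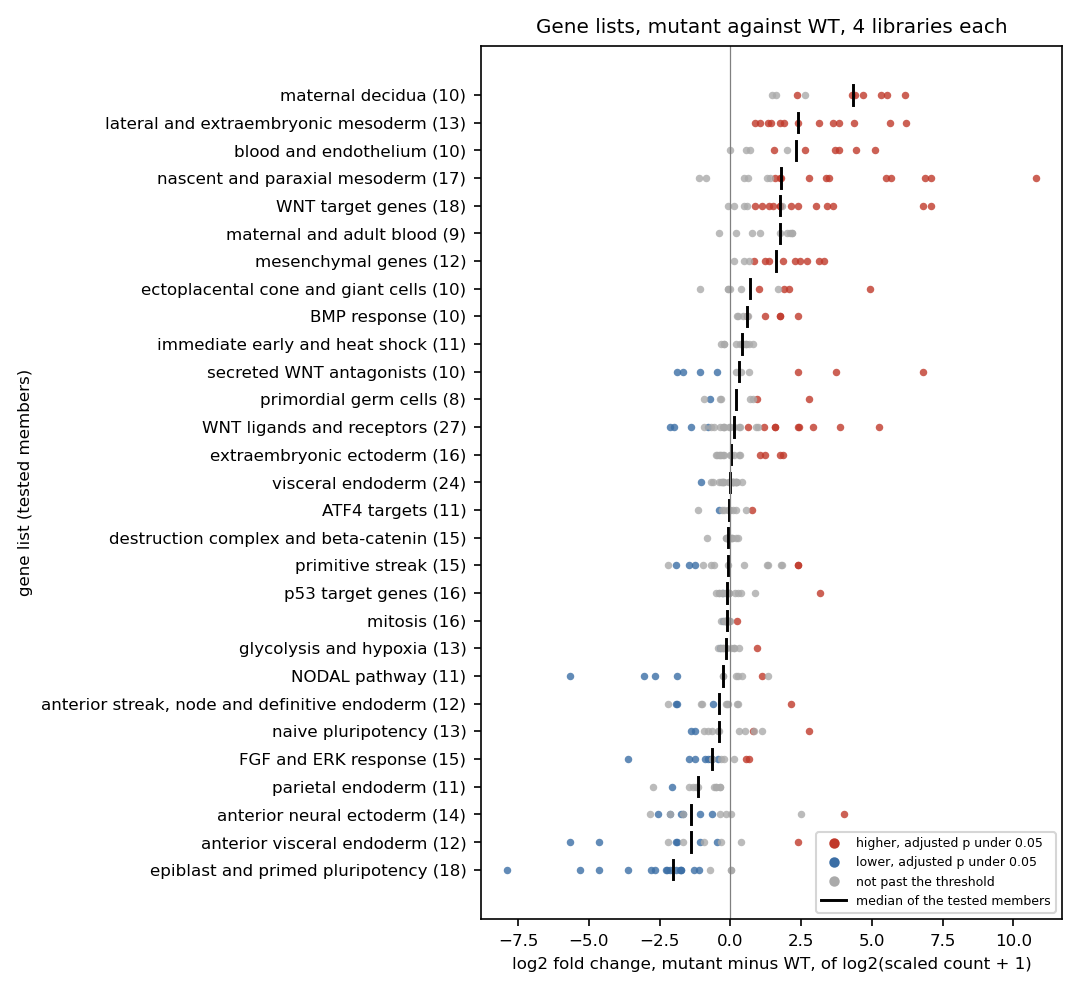
Log2 fold change (mutant minus WT, on log2(scaled count + 1)) of each tested member of the 29 gene lists, 1 row per list with the number of tested members in brackets, red for genes higher and blue for genes lower at an adjusted p under 0.05, grey for the rest, and a black bar at the list median. The lateral and extraembryonic mesoderm list had its 13 tested members higher, and the epiblast list 15 of 18 lower.

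Of 30 tested members of the 2 mesoderm lists, 24 rose and none fell with limma. In the lateral and extraembryonic mesoderm list all 13 tested members were higher (median log2 fold change 2.39; camera adjusted p = 1.05e-11, and adjusted p = 0.0533 with an estimated correlation). 13 higher and 0 lower passed when adjusted over the list alone. Msx1 rose 3.4-fold, Msx2 5.26-fold and Tbx3 2.48-fold, and Isl1, a regulator of cardiac and hindlimb progenitors, from 24.4 ± 13.3 to 305 ± 163. In the nascent and paraxial mesoderm list 11 of 17 were higher and none lower with limma, against 12 higher and 1 lower with DESeq2 (camera adjusted p = 2.16e-08, and adjusted p = 0.12 with an estimated correlation). 13 higher and 1 lower passed when adjusted over the list alone. Msgn1, a presomitic mesoderm factor, rose from 1.71 ± 0.897 to 143 ± 97, Tbx6 11.2-fold (log2 fold change 3.48, SE 0.72, limma adjusted p = 0.0119) and Cdx2 3.37-fold. WT replicate 2 held 6.63 Tbx6 against 58 to 99.4 in the other WT libraries, and Tbx6 rose 6.2-fold without it (log2 fold change 2.63 without WT replicate 2 and 2.79 in the 6 libraries with Y-linked transcripts). The log2 fold change of Msgn1 (5.50) was 6.30 with edgeR and 6.40 with DESeq2. Cyp26a1 was 11333 ± 679.9 in WT and 6653 ± 2295 in the mutants (limma adjusted p = 0.0521, and 0.0114 over the list alone). It passed, lower, with median centring (adjusted p = 0.0334), array weights (0.0384) and DESeq2 (0.00729), and without mutant replicate 1 (0.00349) or 2 (0.0388). Mesp2 was 170.1 ± 108 in WT and 67.2 ± 41.7 in the mutants (log2 fold change -1.13, adjusted p = 0.501). Aldh1a2, which makes retinoic acid, rose from 16.7 ± 8.19 to 1060.0 ± 812, with 2125 in mutant replicate 4 and 338 in mutant replicate 2, an uneven pattern also seen in the decidua genes described later. Its log2 fold change of 5.69 was 4.71 without mutant replicates 4 and 5 and 2.80 with the decidua covariate. Mesp1, which marks the first mesoderm, was 636 ± 442 in WT and 642 ± 227 in the mutants (log2 fold change 1.29, adjusted p = 0.601). That fold change was 1.91 without WT replicate 1, -0.45 without WT replicate 2, 1.95 without WT replicate 5, -0.34 in the 6 libraries with Y-linked transcripts, 0.62 with array weights, 0.01 with edgeR and 0.02 with DESeq2. Without mutant replicates 4 and 5, 10 of 13 and 8 of 17 members of these lists were higher (camera adjusted p = 1.47e-12 and 6.35e-07). With the decidua covariate 5 of 13 and 5 of 17 were (medians 2.12 and 2.34).

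Genes of the first blood and endothelial progenitors were also mostly higher, with 6 of 10 tested members past the threshold and none lower with limma, edgeR or DESeq2 (camera adjusted p = 1.05e-06, and adjusted p = 0.0502 with an estimated correlation). 7 higher and 0 lower passed when adjusted over the list alone, and over all genes 7 and 0 with DESeq2. Lmo2, a cofactor needed for blood formation (chromosome 2, 103957986 to 103981878), had the smallest p of the named genes, rising from 74.1 ± 9.49 to 2565 ± 322 (log2 fold change 5.09, SE 0.14, limma adjusted p = 4.83e-07). Runx1 rose 2.87-fold, Tek 6.22-fold and Gfi1b, at low level, from 1.21 ± 0.449 to 28 ± 7.7, and Tal1 and Kdr rose as well. Kdr was 41.7 in WT replicate 2 against at least 388 in the other WT libraries. Its log2 fold change of 3.84 was 2.91 without WT replicate 2, 2.65 in the 6 libraries with Y-linked transcripts and 4.98 with the decidua covariate, and its call was lost without mutant replicates 4 and 5 (adjusted p 0.0561). Of 10 BMP response genes 5 rose, among them Smad6 (2.32-fold), Msx1, Bambi and Msx2 (camera adjusted p = 3.78e-07, and adjusted p = 0.0701 with an estimated correlation). 7 higher and 0 lower passed when adjusted over the list alone, and over all genes 6 and 0 with DESeq2. Msx1 and Msx2 are also in the lateral and extraembryonic mesoderm list and Bambi in the WNT target list, so these lists are not independent. Bmp4 itself rose from 1044 ± 213 to 3771 ± 1004 (log2 fold change 1.84, SE 0.20, limma adjusted p = 0.000459). In the mesenchymal list 9 of 12 were higher (11 higher and 0 lower adjusted over the list alone, and over all genes 10 and 0 with DESeq2; camera adjusted p = 1.87e-07, and adjusted p = 0.105 with an estimated correlation), including Zeb2 (6.46-fold), Fn1, the fibronectin gene (5.55-fold), Vim (4.85-fold) and Mmp2 (2.58-fold). Without mutant replicates 4 and 5 the counts were 5 of 10, 5 of 10 and 5 of 12 in the same order (camera adjusted p = 2.89e-05, 6.35e-07 and 9.32e-07). With the mean of the maternal decidua list as a covariate they were 2 of 10, 4 of 10 and 1 of 12 (medians 2.38, 0.51 and 1.49, against 2.32, 0.59 and 1.61). There Vim had a log2 fold change of 1.10 against 2.28 (adjusted p = 0.417). The decidua list members Des, Col3a1, Col1a1 and Acta2, which mesenchyme also makes, rose in the same libraries.

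Most epiblast genes fell. Of 18 members of the epiblast and primed pluripotency list 15 were lower with limma and DESeq2 and 14 with edgeR, and none was higher (median log2 fold change -2.03; camera adjusted p = 2.45e-12, and adjusted p = 0.0701 with an estimated correlation). 0 higher and 15 lower passed when adjusted over the list alone. Pou5f1, the gene of the pluripotency factor OCT4 (chromosome 17, 35506018 to 35510772), fell 4.7-fold, from 13147 ± 1019.6 to 2930.2 ± 1028 (log2 fold change -2.23, SE 0.22, limma adjusted p = 0.00032). The DNA methyltransferase genes Dnmt3a and Dnmt3b fell 3.47-fold and 3.37-fold, Sall2 7.02-fold and Slc7a3 39.4-fold. Fgf5 fell from 7456 ± 385 to 970.4 ± 674 (adjusted p = 0.0187), a call lost without WT replicate 4 (adjusted p 0.0506; 8.69e-05 to 0.216 over all settings). Its log2 fold change of -3.61 was -2.59 without mutant replicate 1, -4.67 without mutant replicates 4 and 5, -2.99 with array weights, -2.94 with edgeR, -2.94 with DESeq2 and -4.76 with the decidua covariate. Sox2 was 690.4 ± 166 in WT and 322 ± 110.1 in the mutants (adjusted p = 0.022), a call lost without WT replicate 1, 4 or 5 or mutant replicate 5 (adjusted p 0.0503 to 0.0658). In the 6 libraries with Y-linked transcripts 8 of the 18 were lower, with a list median of -2.02 and a camera adjusted p of 1.55e-10, and without mutant replicates 4 and 5, 14 were. With the decidua covariate 7 were (median -2.50). Naive pluripotency genes changed in both directions (2 higher and 2 lower of 13 with limma; 3 higher and 3 lower adjusted over the list alone, and over all genes 1 and 2 with edgeR and 5 and 3 with DESeq2; median log2 fold change -0.40 and mean 0.03; camera direction lower, adjusted p = 0.694). Nanog fell 2.62-fold (log2 fold change -1.39, SE 0.23, limma adjusted p = 0.00439), and Fgf4 fell. Tet2 rose, a call lost without WT replicate 2, 4 or 5 or mutant replicate 4 (adjusted p 0.0505 to 0.0693), as did Prdm14, lost without WT replicate 4 or mutant replicate 1, 2, 4 or 5 (adjusted p 0.0691 to 0.108) and with a pseudocount of 0.5 (0.0624), quantile normalization (0.0557), array weights (0.0638) and edgeR (0.0689). Of 8 primordial germ cell genes Prdm1 and Prdm14 were higher and Dnd1 lower (camera adjusted p = 0.622). 3 higher and 1 lower passed when adjusted over the list alone, and over all genes 3 and 1 with DESeq2. The Prdm1 call was lost without WT replicate 2, 4 or 5 or mutant replicate 4 or 5 (adjusted p 0.0525 to 0.0786) and the Dnd1 call without WT replicate 1, 4 or 5 or mutant replicate 1, 2, 4 or 5 (adjusted p 0.0561 to 0.123).

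**Figure D3:**
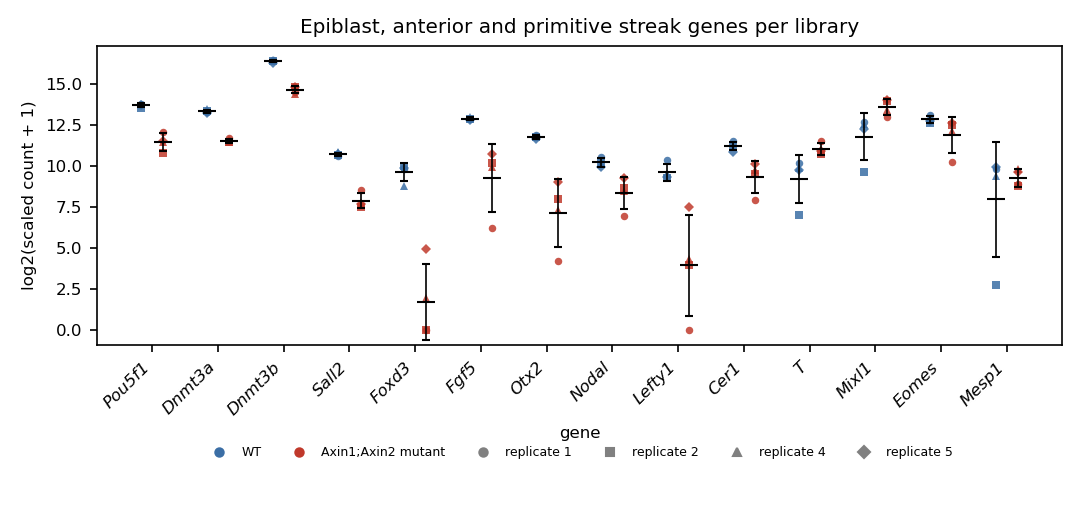
Scaled counts on the log2(value + 1) axis of epiblast, anterior and primitive streak genes in each library, coloured by genotype with the symbol giving the replicate and black bars the mean ± SD of 4 libraries. Pou5f1, Dnmt3a and Dnmt3b were lower in each mutant library than in any WT library, and WT replicate 2 lay far below the other WT libraries for T, Mixl1 and Mesp1.

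Several anterior genes fell in the mutants. In the anterior visceral endoderm list 6 of 12 fell and 1, Dkk1, rose (camera adjusted p = 0.00563, and adjusted p = 0.641 with an estimated correlation). 1 higher and 7 lower passed when adjusted over the list alone, and over all genes 1 and 5 with edgeR. Otx2, a head organizer and anterior epiblast factor (chromosome 14, 48657677 to 48673819), fell from 3473 ± 276 to 232 ± 206 (log2 fold change -4.65, SE 0.84, limma adjusted p = 0.00619), and its exons overlap the antisense gene Otx2os1. Lefty1 fell from 809 ± 316 to 52.7 ± 83.4 (adjusted p = 0.0164) and Cer1 3.69-fold, whereas Hhex was 553 ± 61.8 in WT and 450.2 ± 128 in the mutants (adjusted p = 0.342). The list's call was also lost on the DESeq2 values (adjusted p = 0.0608) and with fry (adjusted p = 0.178; 8.33e-05 to 0.641 over all settings). In the 6 libraries with Y-linked transcripts none of the 12 was lower past the limma threshold, but the list median was -1.23 against -1.39 (camera adjusted p = 0.0116). With the decidua covariate none was lower either (median -2.04). In the 6 libraries the log2 fold changes were -4.73 for Otx2, -5.97 for Lefty1 and -2.01 for Cer1, against -4.65, -5.65 and -1.89 in all 8. For Otx2 it was -3.68 without mutant replicate 1, -5.28 without mutant replicate 5, -5.69 without mutant replicates 4 and 5, -3.92 with array weights, -3.91 with edgeR, -3.90 with DESeq2 and -5.69 with the decidua covariate. For Lefty1 it was -4.34 without mutant replicate 1, -6.83 without mutant replicate 5, -7.60 without mutant replicates 4 and 5, -4.53 with array weights, -3.97 with edgeR, -3.94 with DESeq2 and -8.42 with the decidua covariate, and for Cer1 -2.49 without mutant replicates 4 and 5 and -2.89 with the decidua covariate. In the anterior neural ectoderm list 6 of 14 fell, among them Zic5 (5.93-fold), Zic2 (4.42-fold) and Sfrp2, and Gbx2, expressed posterior to the Otx2 domain, rose 16.2-fold, from 52.3 ± 13.9 to 847 ± 142 (camera adjusted p = 0.00657, and adjusted p = 0.252 with an estimated correlation). 2 higher and 8 lower passed when adjusted over the list alone, and over all genes 2 and 5 with edgeR and 2 and 6 with DESeq2. On the DESeq2 values that list's adjusted p was 0.063 (0.000916 to 0.252 over all settings). Without WT replicate 2, 3 of its 14 members were lower (list median -1.19 against -1.38). In the 6 libraries with Y-linked transcripts 3 were (median -1.21), and without mutant replicates 4 and 5, 8 were (median -1.63). With the decidua covariate 2 were (median -2.25).

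Primitive streak genes went both ways. Of 15 tested, Evx1 (5.22-fold) and Wnt3a rose, and Fgf8 (2.76-fold), Fgf4 and Lhx1 fell (median log2 fold change -0.10 and mean 0.16; camera direction lower, adjusted p = 0.909). 4 higher and 3 lower passed when adjusted over the list alone, and over all genes 2 and 2 with edgeR. The Wnt3a call was lost without WT replicate 5 (adjusted p 0.0541; 0.000391 to 0.249 over all settings). Its log2 fold change of 2.38 was 1.48 in the 6 libraries with Y-linked transcripts and 2.99 with the decidua covariate, and that of Lhx1 (-1.92) -2.60 without mutant replicates 4 and 5 and -2.58 with the decidua covariate. The Fgf4 call was lost without WT replicate 2, 4 or 5 or mutant replicate 2, 4 or 5 (adjusted p 0.0566 to 0.094) and with array weights (0.0505) and the Lhx1 call without WT replicate 1, 4 or 5 or mutant replicate 2 or 4 (adjusted p 0.0588 to 0.109) and with edgeR (0.0546). T, the brachyury gene, was 756 ± 435 in WT and 2127 ± 545 in the mutants (adjusted p = 0.0718), and Mixl1 4527 ± 2599 and 12609 ± 3808 (adjusted p = 0.0806). WT replicate 2 held 129.8 T and 784 Mixl1 against at least 846 and 4833 in the other WT libraries. Without it both genes passed (limma adjusted p = 0.00813 for T and 0.0213 for Mixl1; 0.00813 to 0.459 over all settings for T and 0.0213 to 0.449 over all settings for Mixl1). For T the log2 fold change (1.84) was 1.12 without WT replicate 2 and 1.03 in the 6 libraries with Y-linked transcripts, and that of Mixl1 (1.80) 1.08 without WT replicate 2 and 0.96 in the 6 libraries with Y-linked transcripts. In those 6 T passed (adjusted p = 0.0411). Eomes was 7314 ± 1072 in WT and 4388 ± 2249 in the mutants, and Wnt3 800.0 ± 276 and 533 ± 169.9, both short of the threshold. The anterior streak, node and definitive endoderm list did not pass (1 higher and 3 lower of 12; 1 higher and 3 lower adjusted over the list alone, and over all genes 1 and 2 with edgeR; camera adjusted p = 0.374), with Foxa2 lower (1.54-fold), Cxcr4 higher (4.45-fold) and Gsc at 540.0 ± 202 in WT and 178 ± 139.5 in the mutants (log2 fold change -2.19, adjusted p = 0.122). For Gsc the log2 fold change was -1.23 without mutant replicate 1, -3.08 without mutant replicates 4 and 5, -1.61 with edgeR, -1.60 with DESeq2 and -2.79 with the decidua covariate. The anterior streak list passed, lower, without mutant replicates 4 and 5 (adjusted p = 0.0437) and with the decidua covariate (adjusted p = 0.0211; 0.0211 to 0.793 over all settings).

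Genes of the FGF and ERK response list fell more often than they rose, and NODAL pathway genes changed in both directions. Of 11 NODAL pathway genes, Nodal, Lefty1, Tdgf1 and Gdf3 fell and Cfc1 rose (camera adjusted p = 0.538). 2 higher and 4 lower passed when adjusted over the list alone, and over all genes 1 and 3 with edgeR and 2 and 4 with DESeq2. Nodal had 1192 ± 217 in WT and 371 ± 200.1 in the mutants (log2 fold change -1.88, SE 0.42, limma adjusted p = 0.0164), a call lost without WT replicate 1 (adjusted p 0.0502; 7.12e-05 to 0.165 over all settings). Lefty2 was 1677 ± 1009 in WT and 4177 ± 2994 in the mutants and did not pass (log2 fold change 1.33, adjusted p = 0.405). That fold change was 0.45 without WT replicate 2, 2.11 without mutant replicate 1, 0.37 in the 6 libraries with Y-linked transcripts, 0.27 without mutant replicates 4 and 5 and 0.47 with the decidua covariate. The Tdgf1 call was lost without WT replicate 1, 2, 4 or 5 or mutant replicate 2, with edgeR and in the 6 libraries with Y-linked transcripts (adjusted p 0.0595 to 0.164). The log2 fold change of Tdgf1 (-2.68) was -1.84 without mutant replicate 1, -3.94 without mutant replicates 4 and 5, -2.08 with edgeR, -2.08 with DESeq2 and -4.51 with the decidua covariate, and that of Gdf3 (-3.07) -2.41 in the 6 libraries with Y-linked transcripts. In the FGF and ERK response list 9 of 15 were lower and 2, Spred1 and Fgfr1, higher (camera adjusted p = 0.000199, and adjusted p = 0.241 with an estimated correlation). 2 higher and 10 lower passed when adjusted over the list alone, and over all genes 2 and 10 with DESeq2. The list also holds the receptor gene Fgfr1 and the ligand genes Fgf4, Fgf5 and Fgf8, all among the 9 lower. Fgf5 is also in the epiblast list, Fgf8 in the primitive streak list and Fgf4 in the streak and naive pluripotency lists. The list counts thus do not measure the response to FGF alone. The Spred1 call was lost without WT replicate 5 or mutant replicate 1, 2 or 4, with array weights, in the 6 libraries with Y-linked transcripts and without mutant replicates 4 and 5 (adjusted p 0.0602 to 0.148) and the Fgfr1 call without WT replicate 1, 2, 4 or 5 or mutant replicate 2 or 5, with median centring, in the 6 libraries with Y-linked transcripts and without mutant replicates 4 and 5 (adjusted p 0.0563 to 0.288). Etv5 fell 1.73-fold (log2 fold change -0.79, SE 0.07, limma adjusted p = 0.000178), Spry1 1.59-fold and Etv4 1.36-fold. Without mutant replicates 4 and 5, 5 of the 15 were lower (camera adjusted p = 0.00107), and with the decidua covariate 0 (camera adjusted p = 0.0141).

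In the lists of the extraembryonic lineages 1 to 4 members each passed the limma threshold. Of 24 visceral endoderm genes only Afp did so (DESeq2 called 1 higher and 2 lower), falling 2.08-fold (log2 fold change -1.06, SE 0.13, limma adjusted p = 0.000849), and Ttr was 4771 ± 776 in WT and 4605 ± 976 in the mutants (camera adjusted p = 0.464, and 0.0268 without mutant replicate 2; 0.0126 to 0.992 over all settings). 0 higher and 1 lower passed when adjusted over the list alone. The parietal endoderm list ranked low (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00311, and adjusted p = 0.641 with an estimated correlation) although only Lama1 of 11 passed with limma, with 15476, 26269 and 23089.9 in WT replicates 1, 2 and 4 but 2954 in WT replicate 5, within the mutant range of 2348 to 3984. The Lama1 call was lost without WT replicate 1, 2 or 4 or mutant replicate 1, 2, 4 or 5 (adjusted p 0.0649 to 0.126) and with a pseudocount of 0.5 (0.05004), and its log2 fold change of -2.07 was -2.78 without WT replicate 5. In this list edgeR called 3 genes lower and DESeq2 4, as did limma in the 6 libraries with Y-linked transcripts, and the list did not pass fry (adjusted p = 0.178). Of 16 extraembryonic ectoderm genes Bmp4, Cdx2, Gata3 and Gata2 (2.32-fold) were higher and none lower with limma, edgeR or DESeq2 (camera adjusted p = 0.206, and 0.000159 without mutant replicate 1; 0.000159 to 0.793 over all settings). 4 higher and 0 lower passed when adjusted over the list alone. This list also passed, higher, with array weights (adjusted p = 0.0113) and on the DESeq2 values (adjusted p = 0.0429). The Gata2 call was lost without WT replicate 1 (adjusted p 0.0549; 0.000142 to 0.641 over all settings). Elf5, a marker of that lineage, was 422 ± 78.2 in WT and 344 ± 162 in the mutants (adjusted p = 0.504). Cdx2 is also in the nascent and paraxial mesoderm list. Hand1, of the next list, is also in the lateral and extraembryonic mesoderm list, so these lists are not independent. In the ectoplacental cone and giant cell list 4 of 10 were higher, Phlda2 (4.17-fold), Hand1 (3.7-fold), Gjb2 (2-fold) and Hsd3b6 (camera adjusted p = 0.0165, and adjusted p = 0.241 with an estimated correlation). 4 higher and 0 lower passed when adjusted over the list alone. The preset-correlation call was lost without mutant replicate 5 (adjusted p = 0.111), without the filter on low values (adjusted p = 0.0581) and without mutant replicates 4 and 5 (adjusted p = 0.0811; 0.00159 to 0.241 over all settings). The log2 fold change of Hsd3b6 (4.93) was 4.18 without WT replicate 4, 5.82 without mutant replicate 2, 4.20 without mutant replicate 4, 5.80 in the 6 libraries with Y-linked transcripts, 3.65 without mutant replicates 4 and 5, 5.54 with edgeR, 5.53 with DESeq2 and 0.89 with the decidua covariate.

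Most transcripts of the maternal decidua list, genes of the uterine tissue around the embryo, were higher in the mutant libraries. Of 10 tested list members 7 rose and none fell with limma, and DESeq2 called 8 higher and 0 lower (camera adjusted p = 8.01e-07, and adjusted p = 0.252 with an estimated correlation). 7 higher and 0 lower passed when adjusted over the list alone. In the 6 libraries with Y-linked transcripts 3 of the 10 were higher (list median 4.35 against 4.33), and without mutant replicates 4 and 5, 5 were (median 2.90). Hoxa10, a uterine and posterior mesoderm gene, was 1289.5, 297, 5270.2 and 2622 in mutant replicates 1, 2, 4 and 5 and at most 92.8 in WT. Des was highest in mutant replicate 4 (20271) and lowest among the mutants in replicate 2 (704). Hoxa11 followed the same order, though its exons overlap Hoxa11os. The log2 fold change of Hoxa10 (4.28) was 5.06 without mutant replicate 2, 3.68 without mutant replicate 4, 2.99 without mutant replicates 4 and 5, 4.92 with edgeR, 4.92 with DESeq2 and 0.76 with the decidua covariate. The Des call was lost in the 6 libraries with Y-linked transcripts and without mutant replicates 4 and 5 (adjusted p 0.0762 to 0.0811). Col1a1 rose from 103 ± 56.3 to 6862 ± 2492 and Acta2 from 5.57 ± 4.09 to 294 ± 169, and both are also made by embryonic mesenchyme. Among other named genes that rose, the excess over WT in mutant replicates 1 and 2, relative to replicates 4 and 5, lay in the range of the 7 raised decidua genes (0.0798 to 0.692) for Hsd3b6 (0.203), Aldh1a2 (0.248), Prdm1 (0.309), Gata3 (0.372), Gata2 (0.474), Tet2 (0.557) and Bgn (0.559). With the mean of the decidua list as a covariate, which differs between the genotypes, 58 named calls were lost. The log2 fold change then came nearer 0 by over 1.5 times for Hoxd9 (7.11 against 8.02), Bgn (3.87 against 6.47), Wnt4 (4.12 against 5.23), Aldh1a2 (2.80 against 5.69), Tek (1.79 against 2.64), Gata3 (0.16 against 1.06), Hsd3b6 (0.89 against 4.93), Prdm1 (-0.14 against 0.93), Vim (1.10 against 2.28), Col1a1 (4.46 against 6.15), Acta2 (3.80 against 5.53), Hoxa11 (1.46 against 5.33) and Hoxa10 (0.76 against 4.28), among the called genes that rose. It moved away from 0 by as much for Cdx4, Hoxb6, Cdx1, Fendrr, Hoxb1, Bmp5, Notum, Notumos, Foxd3, Lefty1, Rgs8, Slc7a3, Sez6, Otx2, Miat, Klhl14, Nodal, Lef1, Cer1, Fgf5, Nkd1, Fzd10, Wnt5b, Sfrp2, Wnt3a, Msx2, Lhx1, Gjb2 and Fn1. The decidual prolactin Prl8a2 was 6283 and 6056 in mutant replicates 4 and 5, 135 and 479 in replicates 1 and 2, and up to 1129 in WT, and did not pass (adjusted p = 0.299). None of 9 maternal and adult blood genes passed with limma (0 higher and 0 lower adjusted over the list alone), 4 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The camera adjusted p was 0.0676, and 0.0147, 0.0229 and 0.0126 without WT replicate 1, WT replicate 2 and mutant replicate 1. It was also 0.0182 with median centring, 0.0419 with quantile normalization and 0.0445 in the 6 libraries with Y-linked transcripts (0.0126 to 0.66 over all settings). Hba-a1 was 599 ± 555 in WT and 1987 ± 1023 in the mutants, with an adjusted p of 0.033 without WT replicate 1 (0.033 to 1 over all settings), and Alas2 one of 0.0406 (0.0406 to 0.878 over all settings).

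**Figure D4:**
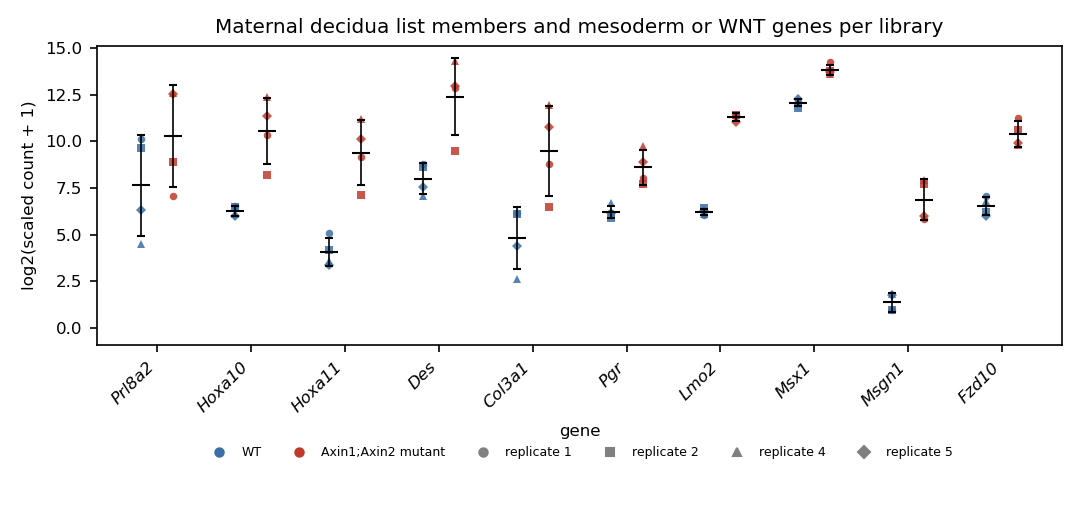
Scaled counts on the log2(value + 1) axis of 6 maternal decidua list members and of Lmo2, Msx1, Msgn1 and Fzd10 in each library, coloured by genotype with the symbol giving the replicate and black bars the mean ± SD of 4 libraries. Hoxa10, Hoxa11, Des and Col3a1 spread widely among the mutants with replicate 2 lowest and replicate 4 highest, whereas Lmo2 and Msx1 varied little.

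In the stress and proliferation lists at most 1 member each was higher and 1 lower with limma. The p53 target list did not pass (1 higher and 1 lower of 16; 1 higher and 0 lower adjusted over the list alone; median log2 fold change -0.11 and mean 0.13; camera direction lower, adjusted p = 0.674), but Cdkn1a, the cell cycle inhibitor p21 gene, rose 8.9-fold, from 188 ± 55.7 to 1685 ± 544 (log2 fold change 3.15, SE 0.26, limma adjusted p = 0.000149). Aen was the lower member, a call lost without WT replicate 1, 2, 4 or 5 or mutant replicate 2, 4 or 5 (adjusted p 0.0575 to 0.121) and with no filter (0.0562). The mitosis list ranked slightly low with a median log2 fold change of -0.11 (camera adjusted p = 0.0167, and adjusted p = 0.641 with an estimated correlation). 1 higher and 3 lower passed when adjusted over the list alone, and over all genes 1 and 3 with DESeq2. Its adjusted p was 0.436 with quantile normalization and 0.104 without mutant replicate 5, 0.0905 on the DESeq2 values and 0.113 with fry (0.0043 to 0.641 over all settings). Plk1 was lower, a call lost without WT replicate 1, 2, 4 or 5 or mutant replicate 1, 4 or 5 (adjusted p 0.0632 to 0.132) and with no filter (0.0536) and quantile normalization (0.12). Within it Ccnb2 was higher (1.16-fold) and lost that call with median centring (adjusted p = 0.171) and without WT replicate 1, 2 or 4 (adjusted p 0.0503 to 0.0529). The glycolysis and hypoxia list (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.544), the ATF4 targets (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.869) and the immediate early and heat shock genes (camera adjusted p = 0.499) did not pass. In these, Egln3 (1.92-fold) and Asns (1.71-fold) rose and Phgdh fell (1.34-fold), while Ldha, at 177144 ± 19135 in WT and 137867 ± 14987 in the mutants, passed with the deposited scaling (adjusted p = 0.0356) and not with quantile normalization (adjusted p = 0.561) or without WT replicate 1, 4 or 5 or mutant replicate 1, 4 or 5 (adjusted p 0.0762 to 0.097). The Egln3 call was lost without WT replicate 5 (adjusted p 0.0562; 0.000524 to 0.141 over all settings). None of 11 immediate early and heat shock genes passed with limma (0 higher and 0 lower adjusted over the list alone), 2 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 1. Ier2 had the smallest p (adjusted p = 0.113), and passed, lower, with median centring (adjusted p = 0.0437; 0.0437 to 0.341 over all settings). Ier3 passed, higher, without mutant replicate 1 (adjusted p = 0.0183), with array weights (adjusted p = 0.0452) and with DESeq2 (adjusted p = 0.037; 0.0183 to 0.931 over all settings).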

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

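The tests on sex, on decidual tissue in the WNT, mesoderm, blood, BMP response, mesenchymal and maternal decidua genes, and on the genes that follow the decidua list were chosen after their results, or values close to them, had been seen. The splits of the samples, the excess ratio over the 2-fold higher genes and the second decidua list were not.

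Regrouping the 8 libraries 4 against 4 in all 35 ways gave as many higher genes (1253) in 1 split, the real one, against 3 at most in any other. The same held for the lower genes (1178, 1 split, highest other 3) and for the 2-fold counts (763 and 538, 1 split each, highest other 3). With 35 splits the smallest share possible is 1 in 35. Every other split mixed the genotypes, so a genotype difference would itself hold its count down, and the splits do not exclude chance. For the lists past the camera threshold, 3 of 35 splits gave at least as many as the 14 of the real split. The highest other also gave 14. Splits that kept 3 libraries of a genotype together still held part of the genotype difference, so this count does not decide either.

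The embryos of the 2 genotypes differed in sex by their Y-linked transcripts, since WT replicates 2 and 5 lacked them. If that were the whole cause of the differences, libraries of 1 kind would not differ by genotype, but among the 6 libraries with those transcripts 1021 genes passed between the genotypes, against 2 at most in the 14 other groupings of 2 against 4. The 1021 genes that passed among libraries of 1 kind argue against sex as the cause of those differences. The other groupings mixed the genotypes, so their low counts add nothing to this. Of the 1021 genes, 970 are among the 2431 past the threshold in all 8. The ratio of the log2 fold change in the 6 to that in all 8 (median 0.997, quartiles 0.889 and 1.09, over 2323 autosomal genes past the threshold, and 0.992 over 104 X- or Y-linked ones) decides nothing, since these genes were chosen for differing in all 8. For genes other than the 1021 sex stays open. Genotype was not tested apart from other differences between these whole embryos, such as their exact stage or the share of each tissue.

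A candidate explanation for the rise of maternal decidua genes is decidual tissue in the mutant samples. In mutant replicates 4 and 5 all 10 of the 10 tested list members lay above each WT library, including Prl8a2 at 6283 and 6056, but these libraries were singled out by this list, so the count decides nothing. Of a second list of decidual and uterine natural killer transcripts 4 were tested and 3 did so, too few to decide. In mutant replicates 4 and 5 Tdo2 was 18751 and 7182 (up to 142 in WT) and Esr1 1804 and 927 (up to 15.2). Prl3c1 was 324 and 472 there (up to 161 in WT). The other member, Greb1, was 1311 and 1806, and already 953 to 1315 in WT. In mutant replicates 1 and 2, 7 of the 10 lay above each WT library, among them Col1a1 (7837 and 3421 against up to 174). Prl8a2 (135 and 479 against up to 1129), Dcn and Cryab did not. Nor did Prl3c1 of the second list (18.3 and 82.9). These few members do not decide between decidual tissue and expression by the embryo's own mesenchyme in either pair.

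Decidual tissue could also have raised other genes. Its transcripts were lower in mutant replicates 1 and 2 than in 4 and 5: over the 7 raised decidua members, the excess over WT in the former was a median of 0.271 times that in the latter (0.0798 to 0.692). Over the 763 genes at least 2-fold higher the median was 1.04 (quartiles 0.521 and 1.64). It was 1.94 over 13 raised WNT target genes and 1.53 over 24 raised mesoderm genes. Over 6 raised blood, 5 BMP response and 9 mesenchymal genes it was 1.30, 1.42 and 1.51. All these genes, like the 7 decidua members, had to pass over all 4 mutants, which favours ratios near 1. The 3 decidua members that did not pass had ratios of -0.0351 (Prl8a2), -0.0283 (Dcn) and -0.00917 (Cryab). Set against the 7 members chosen in the same way, the medians argue against decidua as the cause of these sets as a whole. It stays open for the 240 of the 763 genes at or under the highest decidua ratio, 109 of them at or under the median, and among named genes of any fold for Hsd3b6 (0.203), Aldh1a2 (0.248), Prdm1 (0.309), Gata3 (0.372), Gata2 (0.474), Tet2 (0.557), Bgn (0.559), Hoxd8 (0.622) and Hoxd11 (0.0964). It also stays open for the list members Hand2 (0.112), Snai2 (0.200) and Dll1 (0.535).

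A single library stood far from the other 3 of its genotype in 24 of 300 groups examined, where chance alone flags about 1 in 20 groups, or 15. WT replicate 2 was lowest in T (129.8 against 846 to 1133), Mixl1 (784 against 4833 to 6604), Lefty2 (188.5 against 1941 to 2388), Mesp1 (5.68 against 658 to 974), Wnt5b (144 against 288 to 317), Zeb2 (80.5 against 211 to 236) and Ldha (148595 against 184876 to 189413). WT replicate 2 was highest in Hapln1 (5.68 against 0), Ttr (5935 against 4370.2 to 4403) and the mean log2 value of the visceral endoderm list (12.87 against 12.58 to 12.62). WT replicate 1 was highest in Platr10 (801 against 407 to 431). WT replicate 4 was lowest in Axin1 (2963 against 4884 to 5274) and Foxd3 (437 against 898 to 996). WT replicate 4 was highest in Cdx4 (2.6 against 0) and Hoxb2 (3.465 against 0.928 to 1.18). WT replicate 5 was highest in Hoxb6 (1.18 against 0). Mutant replicate 1 was lowest in Dkk1 (4406 against 8645 to 9519). Mutant replicate 1 was highest in Wnt5a (2818 against 1739 to 1823) and Dnmt3a (3299 against 2766 to 2850.3). Mutant replicate 2 was lowest in Hoxd9 (757 against 917 to 933), Sfrp2 (115 against 225 to 247) and Asns (6684 against 7669.9 to 7746). Mutant replicate 2 was highest in Ldha (160203 against 128026 to 131640.4). Mutant replicate 5 was lowest in Lmo2 (2083 against 2687 to 2751). WT replicate 2 accounts for 10 of the 24, among them the streak genes T, Mixl1, Lefty2 and Mesp1. For Cdx4, Hapln1, Hoxb6 and Hoxb2 the gap rests on a few reads.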

How the results depend on the processing

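The fits on the 6 libraries with Y-linked transcripts, without mutant replicates 4 and 5 together and with the decidua mean as a covariate were chosen after seeing the data. Axin1 stayed lower and past the threshold in every fit (log2 fold change -1.60 to -0.99, adjusted p up to 0.0498) and Axin2 stayed short of it (0.24 to 0.61). Leaving out each library gave 853 to 1295 higher and 734 to 1144 lower genes, and 584 to 873 and 416 to 542 at 2-fold. The lower count moved most without WT replicate 1 (734) and WT replicate 4 (743). The 6 libraries with Y-linked transcripts gave 528 higher, 493 lower, 418 and 312 at 2-fold. Without mutant replicates 4 and 5 these were 707, 723 and 448 (2-fold higher), and with the decidua covariate, which differs between the genotypes and takes much of their contrast with it, 148, 143, 136 and 134. Fewer samples or fewer free degrees make such fits call less. Gene lists past the threshold numbered 0 with an estimated correlation (the cause was not tested) and 12 to 16 when a library was left out. For blood and endothelium the estimated correlation was -0.00557, under the preset 0.01. Its camera p still rose from 2.88e-07 to 0.00173, so for that list correlation among its genes does not account for the rise.

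Among 118 named genes other than Axin1 and Axin2, 83 of 102 calls held in each of the 18 alternatives fixed beforehand that fit genes (Foxr2, Gfi1b and Prdm14 had no value with a mean of at least 50), 19 were lost in at least 1, 7 genes gained a call and none turned; quantile normalization or median centring ended 4 calls. Of the 14 lists, 9 kept their call in all 20 fixed alternatives, which add 2 list tests, but the estimated correlation. With the decidua covariate 58 named calls were lost, and Prdm1 (-0.14) and Plk1 (8e-04) turned, as did the visceral endoderm (adjusted p = 0.0126), mitosis (0.488) and glycolysis and hypoxia (0.0208) lists; the cause was not tested. The replicate block gave 910 higher and 789 lower genes, ended 12 named calls, started 1 (T) and changed no list. Same-numbered WT and mutant libraries deviated with correlations of -0.04, -0.17, -0.19 and -0.05, and 0 of 8 libraries correlated best with their own number. This gave no sign that the numbers pair the embryos. With so few libraries a shared litter or day could be missed, so pairing is not excluded. Sex as a covariate was not run, since it was planned only if both genotypes held libraries of either kind. DESeq2 gave no adjusted p for 14 genes. Depth limits only low genes: Cdx4 and Hoxb6 rest on 3 reads and 1 read in WT.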

Other observations

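The groups and tests described here, all of them, were chosen after results had been seen, and 2 of 3 gene groups so tested are described. Hox genes, which pattern the trunk from front to back, rose across all 4 clusters. The data held 36 Hox genes, of which 25 met the filter and were tested. Of these, 22 were higher in the mutants with limma (camera p = 2.96e-22, and p = 0.00100 with an estimated correlation, for this 1 group). Several, among them Hoxc5, Hoxa2, Hoxb5, Hoxb3 and Hoxd8, stayed under a scaled count of 10 in each WT library. Such genes met the filter through the mutants alone and could not have passed as lower. The counts and the camera p were thus partly fixed by the filter. All 9 tested genes of paralogue groups 1 to 4 were higher, 5 of 6 in groups 5 to 8 and 8 of 10 in groups 9 to 13. Hoxd1 rose from a mean of 12.1 to 497, Hoxd8 from 2.37 to 261 and Hoxb9 from 2.54 to 117. Hoxd9 was nearly level among the mutants (757 to 933), whereas Hoxd11 ranged from 23.9 in mutant replicate 2 to 727 in mutant replicate 4.

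Of 12 epithelial genes tested 6 fell, none rose and 6 did not pass with limma (camera p = 3.23e-05, and p = 0.198 with an estimated correlation). Cdh1, the E-cadherin gene, was 23790.0 ± 1467 in WT and 16013 ± 4326 in the mutants (limma adjusted p = 0.0410), and Epcam 10150.2 ± 391 and 6308 ± 1244 (adjusted p = 0.00689). Grhl2, Esrp1, Crb3 and F11r also fell.

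Posterior Hox genes are made in the uterus as well, so decidual tissue may account for part of the Hox rise. Over the 14 raised genes of groups 1 to 8 the excess over WT in mutant replicates 1 and 2 was a median of 1.61 times that in replicates 4 and 5 (quartiles 1.17 and 2.06). These genes and the decidua genes (0.271) were both chosen for passing over all 4 mutants, which favours ratios near 1. Set side by side, the medians argue against a decidual source for groups 1 to 8 as a set. That source stays open for Hoxd8 (0.622), in the range of the decidua genes. Over the 8 raised genes of groups 9 to 13 the median was 0.395 (quartiles 0.195 and 1.17), too wide to decide, so decidual and embryonic sources cannot be told apart for that set.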
